A study of Mus musculus with 24 samples.

How the data were processed

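Liver RNA of C57BL/6 mice was measured by sequencing of polyadenylated RNA in 24 libraries. Per the labels, they form 8 groups of 3 replicates: wild type mice and mice with a human CAR knock-in (hCAR-TG), at day 5 and day 60 of age, given corn oil or a CAR ligand. CAR, the constitutive androstane receptor, is the product of Nr1i3. The ligand was TCPOBOP, an agonist of mouse CAR, in wild type mice and CITCO, an agonist of human CAR, in hCAR-TG mice, so receptor and ligand always differ together. Per the labels' protocols, RNA was extracted with RNA Bee and stranded libraries were made with a TruSeq kit. Per the submitters' processing notes, the genome build was mm10. The aligner, quantification tool, their versions and the gene annotation were not given in the sources used here. The labels give no dose and do not say whether replicates are separate animals, so every p-value measures only the spread between these samples.

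The values used are FPKM per gene, deposited as one table per library; per the file headers each entry has an FPKM, the bounds of its interval and a status. Each table holds 24885 entries with 24342 symbols. Of the symbols, 281 were found at several loci, and entries of such a symbol were summed. The exception was 27 date-like entries (symbols altered by a spreadsheet), which were kept apart by locus. Left out were 5 genes with a failed estimate in a library (Ceacam1, Gm2083, Mif4gd, Mup16 and Tle1), leaving 24339 genes. FPKM totals were 451546 to 502499 per library. Read totals were not used here, so the absolute depth is unknown. Interval widths of 3457 genes gave relative depths of 0.851 to 1.086. Library groups were checked against Xist (at most 0.016 FPKM) and the Y-linked gene Ddx3y (3.28 to 12.66 FPKM), so all libraries carry male RNA and no sex covariate was fitted. Coordinates are those of the files.

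Genes with at least 1 FPKM in at least 3 of the 24 libraries were tested (12282 genes). log2(FPKM + 1) values were fitted with limma (lmFit, then eBayes with trend and robust) in a single model of the 8 groups with 16 residual degrees of freedom. Tests were two-sided, with the Benjamini-Hochberg adjustment over all tested genes and a call at adjusted p under 0.05. The 12 comparisons were the ligand against corn oil in each genotype and age, the differences of those responses between ages and between receptor and ligand pairs, and the corn oil groups compared between genotypes and between ages. Log2 changes are given with their standard error (SE) and FPKM with the SD over 3 replicates. The pseudocount makes log2 changes smaller than the FPKM ratio for genes near 1 FPKM. For 3 against 3 libraries, complete separation of the groups occurs by chance in 10% of genes. The fit was tried on simulated libraries, drawn from the group means with independent normal noise of each gene's fitted spread. Changes were put into a small set of better expressed genes. Of log2 changes of 0.5, 74.2% to 81.8% were recovered, and 2.63% to 4.66% of calls were false. Outlying libraries, correlated genes and widespread changes were not simulated, so these rates need not hold for the real libraries.

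Before the data were examined, 36 gene lists were fixed from textbook knowledge: 8 families of drug-processing genes (255 genes, 220 tested), CAR targets, metabolic and stress pathways, cell cycle, and cell type, sex and tissue markers. A gene can be in several lists. Lists with at least 5 tested members (32 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each was also tested with an estimated correlation. Counts of called members are given as adjusted over all genes, and, where stated, as adjusted over the list alone. The muscle and the mitochondrially encoded lists had 0 tested members.

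Genes were named by a rule fixed at the same time. For each treatment comparison these are Nr1i3, Nr1i2 and Cyp2b10, the 8 largest rises and 8 largest falls among called genes with non-overlapping groups (predicted genes left out), and up to 4 called members per list with the lowest adjusted p. For a difference between responses they are Cyp2b10 and the 6 drug-processing genes with the largest difference each way. For the corn oil comparisons they are Nr1i3, Cyp2b10, the 6 largest changes each way and up to 3 members per list. The text prints part of these.

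Alternatives were rescaling by median of ratios, a pseudocount of 0.1, no filter, a filter at 5 FPKM, a replicate block, a fit of the compared libraries alone, array weights, a constant prior, a call that also needs a 2-fold change, and leaving out each replicate in turn. A number that closes the read file names (meaning not stated, called the suffix here) was also fitted as a factor where it could be told apart from the comparison. Leaving out 3 libraries with pancreatic transcripts was added and chosen after seeing the data. Where groups differed, each count was set against other splits of the same libraries: all 10 splits for a pair of groups, 100 drawn of 200 for a difference of responses. Tools were R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.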

Results

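Age separated the libraries most: the first principal component held 72.3% of the variance and the second 12.2%. Cyp2b10, the P450 gene most used as a readout of CAR, was higher with the ligand in every genotype and age, but its corn oil level differed widely between groups. Reads shared among close relatives (Cyp2b, Cyp2c, Cyp3a, Gstm, Gsta, Sult2a, Mup, Defa and globin genes) leave the values of single members of these families uncertain. Nr1i3 counts in hCAR-TG mice are also uncertain, since reads of the human gene may not be counted on the mouse genome.

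**Figure D1:**
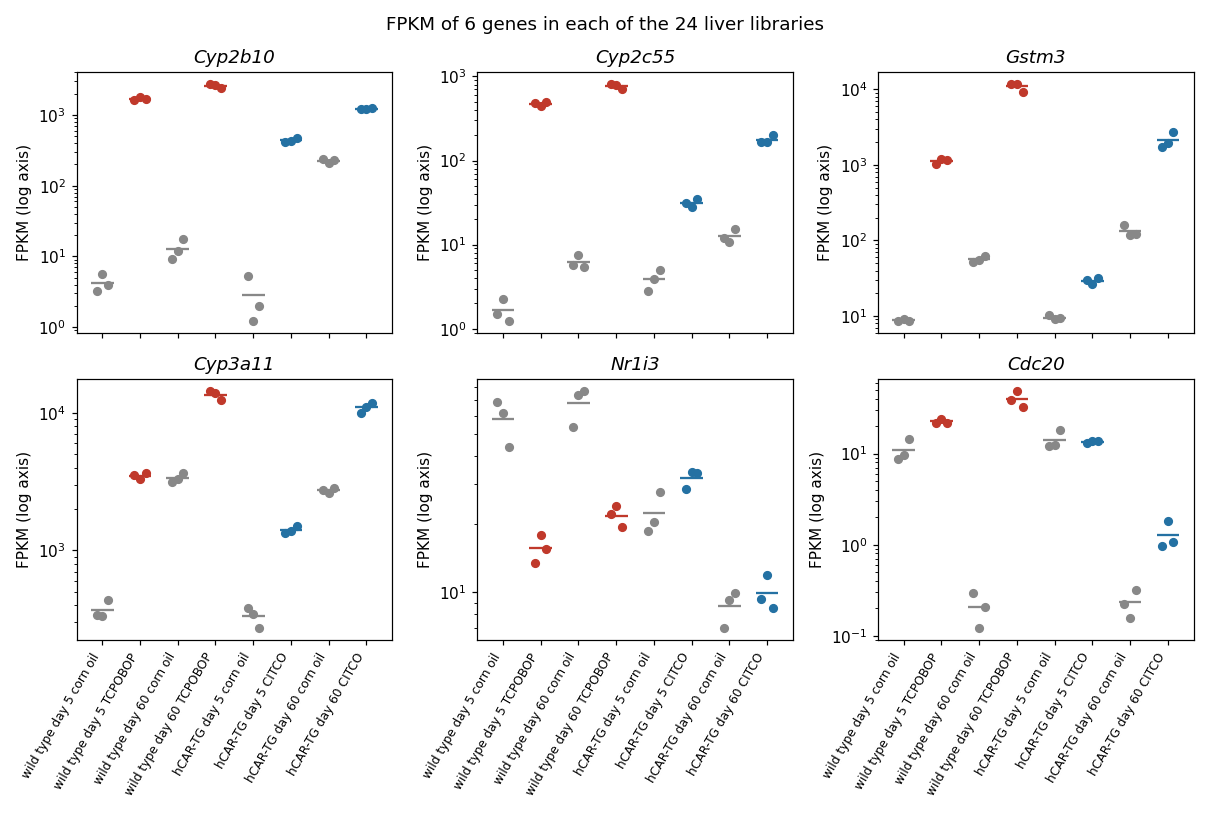
FPKM of 6 genes in each of the 24 libraries, by genotype, age and treatment, on a log axis. Horizontal lines are group means of 3 libraries.

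In newborn wild type liver (day 5), the largest single rises with TCPOBOP were in genes of P450 oxidation and glutathione conjugation. Cyp2b10 rose from 4.26 ± 1.18 to 1694 ± 82.4 FPKM (mean ± SD, n = 3 per group; log2 change 8.35 ± 0.26, ± SE; limma adjusted p = 5.07e-15). The P450 genes Cyp2c29 (7.92 ± 0.39) and Cyp2c55 (7.49 ± 0.16) rose with it, as did Gstm3 (6.84 ± 0.14) and Gstt3 (5.15 ± 0.27), which encode glutathione S-transferases, and the aldehyde dehydrogenase gene Aldh1a7 (5.61 ± 0.17). Outside drug metabolism, the pancreatic lipase-related gene Pnliprp1 rose to 1536 ± 168 FPKM (5.29 ± 0.35). The largest falls were in BC089597 (-3.19 ± 0.21), the ciliary dynein gene Dnaic1 (-2.69 ± 0.10), the Wnt antagonist Notum (-2.44 ± 0.09), the anion transporter Slc22a7 (-2.37 ± 0.14), Ugt3a2 (-2.27 ± 0.12) and the tight junction gene Cldn2 (-1.98 ± 0.11). Nr1i3 itself fell from 58.0 ± 12.8 to 15.7 ± 2.19 FPKM (-1.81 ± 0.18, limma adjusted p = 1.33e-07), while Nr1i2, which encodes the related receptor PXR, was at 0.23 ± 0.11 (limma adjusted p = 0.108).

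Among the CAR targets known from adult liver, 32 of 35 rose in these newborns and 0 fell (camera adjusted p = 4.19e-31, and adjusted p = 0.000922 with an estimated correlation). In brackets after a list stand its camera adjusted p and the adjusted p with an estimated correlation. In the P450 list 34 of 47 rose and 2 fell (1.36e-12, and 0.00937 with an estimated correlation), including Cyp3a11, the main CYP3A gene of adult mouse liver (3.25 ± 0.11). Among other phase I enzymes 35 of 58 rose and 10 fell (2.66e-06, and 0.016 with an estimated correlation), with the carboxylesterase gene Ces2a (4.22 ± 0.12), Aldh1a1 (4.30 ± 0.18) and the epoxide hydrolase gene Ephx1 (2.65 ± 0.09) higher. Glutathione S-transferase genes rose in 20 of 27 cases and fell in 0 (2.03e-11, and 0.0107 with an estimated correlation). Sulfotransferase genes rose in 12 of 17 with 1 lower (0.000221, and 0.0496 with an estimated correlation). UDP-glucuronosyltransferase genes were lower in 3 of 20 and higher in 12, among them Ugt2b36 (1.86 ± 0.09). The list's camera adjusted p = 0.000535 was lost with an estimated correlation (adjusted p = 0.194). The efflux pump genes Abcc4 (3.38 ± 0.08) and Abcc3 (3.90 ± 0.12) rose, although efflux transporters as a list (6 of 17 higher, 4 lower) were not called (camera adjusted p = 0.124). Targets of the oxidative stress factor NRF2, which share members with the transferases, rose in 11 of 14 cases (4.34e-07, and 0.00937 with an estimated correlation), among them Srxn1 (1.37 ± 0.09).

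Lower in the same newborns were 18 of 34 genes of PPARa and fatty acid oxidation, with 3 higher (camera adjusted p = 4.42e-06, and adjusted p = 0.462 with an estimated correlation), including Acot3 (-1.77 ± 0.19) and Hadhb (-0.77 ± 0.08). Gluconeogenic genes such as Fbp1 (-0.95 ± 0.09) fell in 5 of 15 cases with 1 higher (0.00564, and 0.109 with an estimated correlation). Stellate cell markers such as Lrat (-0.98 ± 0.14) fell in 6 of 15 (0.000993, and 0.312 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 24 cases (0.00192, and 0.631 with an estimated correlation), for example Insig1 (1.20 ± 0.16), and cell cycle genes in 17 of 42 with 1 lower (0.0109, and 0.675 with an estimated correlation). In total 4408 of 12282 genes were called, 3022 higher and 1386 lower (309 and 82 by at least 2-fold). Of all tested genes 47.6% had non-overlapping groups, where chance gives 10%. Of the 220 drug-processing genes, 132 were higher and 29 lower (171 called when adjusted over the list alone). After rescaling, 4389 genes were called with 53.4% higher against 68.6% as deposited, so the balance of directions rests on the scaling. The suffix cannot be told apart from treatment here.

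In adult wild type liver (day 60), TCPOBOP raised many drug-metabolism genes and most listed cell cycle genes, and lowered other drug-metabolism genes. Of the 132 drug-processing genes higher at day 5, 90 were higher at day 60 (67 if independent) and 17 were lower. Cyp2b10 rose from 12.9 ± 4.16 to 2596 ± 180.0 FPKM (7.59 ± 0.26; n = 3 per group, limma adjusted p = 1.05e-14). Gstm3 (7.56 ± 0.14), Gsta1 (7.28 ± 0.18), Cyp2c55 (6.75 ± 0.16), the aldo-keto reductase gene Akr1b7 (6.49 ± 0.21), Pnliprp1 (6.12 ± 0.35), Cyp2b13 (5.81 ± 0.19) and the estrogen sulfotransferase gene Sult1e1 (5.54 ± 0.22) followed. The steroid dehydrogenase gene Hsd3b5, typical of male liver, fell from 116 ± 44.2 to 0.759 ± 0.883 FPKM (-6.10 ± 0.32). The uptake transporter Slco1a1 (-4.04 ± 0.21), the hepcidin gene Hamp2 (-3.51 ± 0.39), the ribonuclease genes Rnase4 (-3.16 ± 0.15) and Ang (-3.04 ± 0.12), and Cyp4a10 (-2.87 ± 0.37), a fatty acid hydroxylase under PPARa, also fell. Nr1i3 fell from 68.2 ± 12.9 to 21.8 ± 2.34 FPKM (-1.59 ± 0.18) and Nr1i2 rose (0.50 ± 0.11, limma adjusted p = 0.000796).

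Cell cycle genes rose in 41 of 42 cases (median log2 change 2.20; camera adjusted p = 5.28e-27, and adjusted p = 0.0649 with an estimated correlation), among them Cdc20 (5.08 ± 0.17), Cdca3 (4.07 ± 0.15), the cyclin gene Ccna2 (3.07 ± 0.12) and Cdk1 (2.91 ± 0.10). In the p53 and apoptosis list, 8 of 13 rose (0.00638, and 0.122 with an estimated correlation), with Gadd45b (4.27 ± 0.24) and Gadd45a (2.86 ± 0.10) highest. CAR targets rose in 34 of 35 cases (1.71e-20, and 0.00876 with an estimated correlation) and NRF2 targets in 11 of 14 (1.28e-05, and 0.0277 with an estimated correlation). Glutathione S-transferase genes rose in 17 of 27 cases with 2 lower (3.58e-06, and 0.0649 with an estimated correlation), and sulfotransferase genes in 11 of 17 with 2 lower (0.0203, and 0.201 with an estimated correlation), Sult3a1 by 3.92 ± 0.13. The P450 list moved both ways, with 29 of 47 higher and 15 lower, and was not called (camera adjusted p = 0.193). Neither were other phase I enzymes (30 of 58 higher, 17 lower, 0.176) nor UDP-glucuronosyltransferases (8 of 20 higher, 4 lower, 0.474). Other conjugation enzymes fell in 10 of 17 cases with 4 higher (0.00973, and 0.122 with an estimated correlation), for example the betaine methyltransferase gene Bhmt (-2.45 ± 0.16).

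Metabolic lists moved as well. Cholesterol synthesis genes rose in 20 of 24 cases (camera adjusted p = 0.00358, and adjusted p = 0.572 with an estimated correlation). Lipogenic genes were higher in 9 of 17 cases and lower in 2, such as Elovl6 (2.62 ± 0.20) and Pnpla3 (2.27 ± 0.12), though the list was not called (0.0507). PPARa and fatty acid oxidation genes fell in 20 of 34 cases with 2 higher (3.58e-06, and 0.381 with an estimated correlation). Gluconeogenic genes fell in 9 of 15 with 1 higher (0.00225, and 0.0649 with an estimated correlation), including Pck1 (-1.47 ± 0.18). Bile acid synthesis genes fell in 9 of 15 with 2 higher (0.0015, and 0.0252 with an estimated correlation), including Cyp7b1 (-2.43 ± 0.22). Nuclear receptor genes were lower in 8 of 26 and higher in 5 (0.0462, and 0.183 with an estimated correlation), Ppara at -1.67 ± 0.13. After rescaling 14 were lower. Male-biased liver genes fell in 9 of 15 cases with 1 higher (3.58e-06, and 0.183 with an estimated correlation). Female-biased genes rose in 10 of 14 with 2 lower (2.43e-05, and 0.0602 with an estimated correlation), including Hao2 (2.63 ± 0.08). Erythroid markers fell in 7 of 16 cases (0.00973, and 0.542 with an estimated correlation), while Kupffer cell, neutrophil and lymphocyte markers were not called as lists. The test called 5801 genes, 3855 higher and 1946 lower (638 and 196 by at least 2-fold). Of all tested genes 60.0% had non-overlapping groups (10% by chance). Of the drug-processing genes 112 were higher and 60 lower (177 called when adjusted over the list alone). Rescaled values gave 6014 genes with 51.0% higher against 66.5% as deposited.

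**Figure D2:**
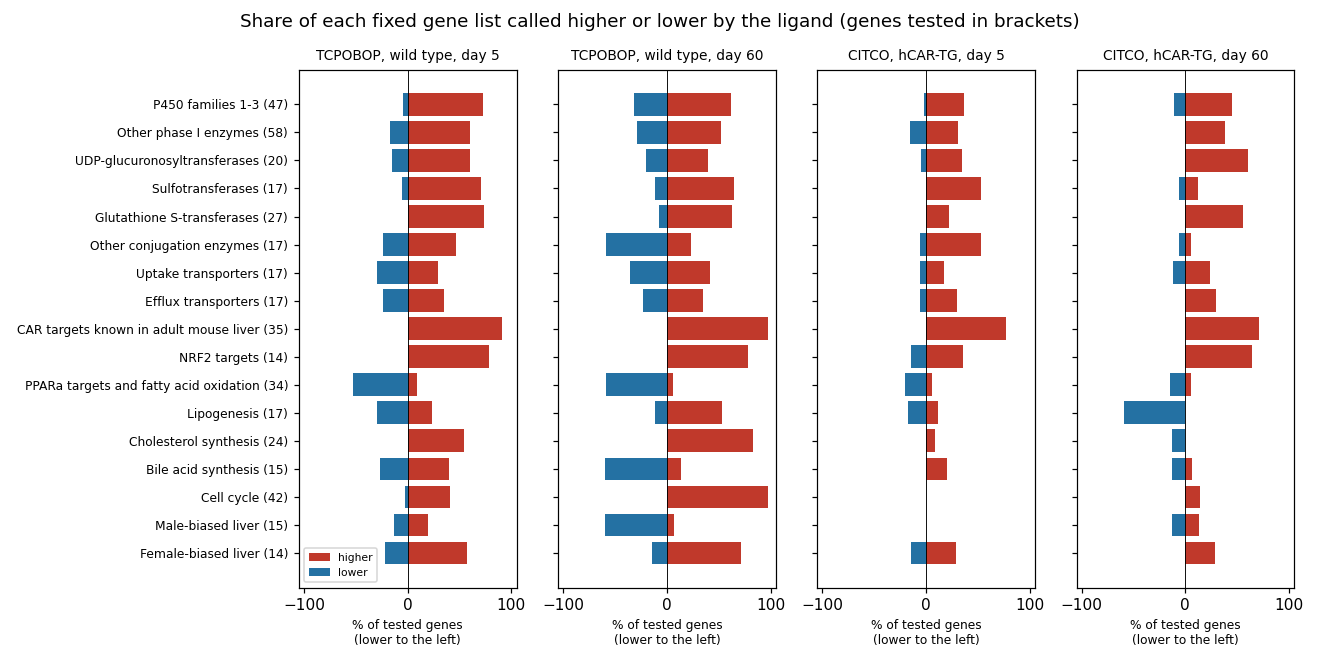
Share of the tested genes of each fixed list that was called higher or lower with the ligand, in the 4 treatment comparisons. The number of tested genes is in brackets.

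In newborn hCAR-TG liver, the largest single rises with CITCO were in Cyp2b and Cyp2c genes. Cyp2b10 rose from 2.81 ± 2.13 to 435 ± 28.0 FPKM (6.98 ± 0.26; n = 3 per group, limma adjusted p = 8.44e-13). Next were Cyp2c29 (6.10 ± 0.39), Cyp2c50 (4.78 ± 0.41), Cyp2c54 (4.41 ± 0.38), Cyp2c55 (2.73 ± 0.16), Aldh1a7 (2.71 ± 0.17), the bile acid sulfotransferase gene Sult2a5 (2.69 ± 0.10) and Cyp1a2 (2.68 ± 0.12). Of the 8 largest falls 7 were in genes of the intestine, among them Lypd8 (-3.37 ± 0.23) and the defensin genes Defa24 (-2.69 ± 0.29), Defa2 (-2.02 ± 0.17) and Defa20 (-2.01 ± 0.16). These 7 were higher in all 3 corn oil libraries than in the CITCO libraries. Defa24 reached 14.5 FPKM in corn oil replicate 3 against at most 0.495 in the libraries of the other groups. Spink4, also among the 7, was less distinct, at 1.54, 3.94 and 21.7 FPKM in the corn oil libraries. It reached 4.41 FPKM in wild type TCPOBOP replicate 3 at day 5. The G protein regulator gene Rgs16 also fell (-3.25 ± 0.47). Nr1i3 (0.52 ± 0.18, limma adjusted p = 0.0538) and Nr1i2 (0.30 ± 0.11, limma adjusted p = 0.0614) were not called.

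CAR targets rose in 27 of 35 cases (camera adjusted p = 1.06e-33, and adjusted p = 0.000585 with an estimated correlation) and sulfotransferase genes in 9 of 17 (1.17e-06, and 0.0238 with an estimated correlation), among them Sult2a1 (1.92 ± 0.18). P450 genes rose in 17 of 47 with 1 lower (1.32e-07, and 0.0665 with an estimated correlation), including Cyp3a11 (2.09 ± 0.11) and Cyp1a1 (1.60 ± 0.06). Smaller list shifts were lost with an estimated correlation. These were other phase I enzymes (18 of 58 higher, 9 lower, camera adjusted p = 0.032, and adjusted p = 0.292 with an estimated correlation), UDP-glucuronosyltransferases (7 of 20 higher, 1 lower, 0.0108, then 0.314), glutathione S-transferases (6 of 27 higher, 0.0109, then 0.314), other conjugation enzymes (9 of 17 higher, 1 lower, 0.00895, then 0.143) and NRF2 targets (5 of 14 higher, 2 lower, 0.0289, then 0.235). Ugt1a9 (2.13 ± 0.18), Gstt3 (2.57 ± 0.27) and the NRF2 target Nqo1 (1.31 ± 0.16) were among the members that rose. Lower were 8 of 16 endothelial markers (3.79e-07, and 0.143 with an estimated correlation), such as Clec4g (-0.59 ± 0.09), and 5 of 14 neutrophil markers (1.8e-05, and 0.314 with an estimated correlation), such as Ngp (-0.89 ± 0.24). Fetal liver genes fell in 7 of 15 cases with 1 higher (0.0362, and 0.143 with an estimated correlation) and immediate early and heat shock genes in 5 of 21 (0.0213, and 0.235 with an estimated correlation). Of 42 cell cycle genes, 0 were called. Among 4 tested sex-linked genes, Uty (0.46 ± 0.14) and Eif2s3y (0.61 ± 0.19) were called higher. Corn oil replicate 3 carries this: Eif2s3y was at 6.63 FPKM there and at 16.56 and 14.16 in the other replicates. Without it the changes were 0.20 for Uty and 0.24 for Eif2s3y and were not called (limma adjusted p = 0.107 and 0.149).

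The test called 2099 genes, 1016 higher and 1083 lower (70 and 46 by at least 2-fold), and 35.0% of all tested genes had non-overlapping groups (10% by chance). Among drug-processing genes 74 were higher and 14 lower (99 called when adjusted over the list alone). Corn oil replicate 3 stands apart (deviation from its group 0.26, against 0.0976 to 0.180 for the other libraries), and without it the count was 1813. Of the 2099 genes, 1319 then kept call and direction. Without CITCO replicate 2 or replicate 3 the count fell to 1182 and 1147. It was 596 in a fit of these 6 libraries alone, 5259 with array weights and 4793 (59.5% higher) with the suffix as a factor, where corn oil replicate 3 alone stands for its group, so its size is uncertain by several fold. Rescaled values gave 2242 with 40.2% higher against 48.4%.

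In adult hCAR-TG liver, the largest single rises with CITCO were in genes of glutathione conjugation and P450 oxidation. Cyp2b10 rose from 225 ± 16.5 to 1226 ± 31.0 FPKM (2.44 ± 0.26; n = 3 per group, limma adjusted p = 3.11e-06). Larger rises were seen in Gsta1 (4.25 ± 0.18), Gstm3 (3.98 ± 0.14), Cyp2c55 (3.72 ± 0.16), the membrane glycoprotein gene Prom1 (3.23 ± 0.18) and Akr1b7 (3.08 ± 0.21). The largest falls were in Cyp4a10 (-1.85 ± 0.37), the mitochondrial carrier gene Slc25a25 (-1.84 ± 0.32), the nuclear receptor gene Ppard (-1.83 ± 0.16), the endoplasmic reticulum stress genes Sdf2l1 (-1.69 ± 0.18) and Creld2 (-1.63 ± 0.18), and the fatty acid desaturase gene Scd1 (-1.60 ± 0.21). Nr1i3 (0.18 ± 0.18, limma adjusted p = 0.668) and Nr1i2 (0.32 ± 0.11, limma adjusted p = 0.0842) were not called.

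CAR targets rose in 25 of 35 cases (camera adjusted p = 4.68e-48, and adjusted p = 6.88e-05 with an estimated correlation). Glutathione S-transferase genes rose in 15 of 27 (3.86e-18, and 0.00115 with an estimated correlation), other phase I enzymes in 22 of 58 (7.78e-14, and 0.000537 with an estimated correlation) and UDP-glucuronosyltransferases in 12 of 20 (7.23e-14, and 0.00511 with an estimated correlation), with 0 lower in each. Por, the electron donor of the P450 enzymes, rose by 2.12 ± 0.15 and Ces2a by 1.84 ± 0.12. P450 genes rose in 21 of 47 with 5 lower (6.46e-11, and 0.0104 with an estimated correlation). NRF2 targets rose in 9 of 14 (8.05e-13, and 0.000537 with an estimated correlation), efflux transporters in 5 of 17 (0.000215, and 0.036 with an estimated correlation) and female-biased genes in 4 of 14 (3.92e-06, and 0.0225 with an estimated correlation). Lipogenic genes fell in 10 of 17 cases (6.46e-11, and 0.0294 with an estimated correlation), including Srebf1, the transcription factor of lipogenesis (-1.08 ± 0.20), and Acly (-0.94 ± 0.15). Gluconeogenic genes fell in 5 of 15 (0.000694, and 0.0353 with an estimated correlation).

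Other shifts in these adults were lost with an estimated correlation. They were in cholesterol synthesis (3 of 24 lower, camera adjusted p = 1.24e-07, and adjusted p = 0.291 with an estimated correlation), cell cycle (6 of 42 higher, 11 after rescaling, 3.96e-08, then 0.346), sulfotransferases (2 of 17 higher, 1 lower, 0.0436, then 0.291), PPARa and fatty acid oxidation (2 of 34 higher, 5 lower, 0.0318, then 0.712), and markers of stellate cells (3 of 15 lower, 0.000144, then 0.218), endothelial cells (2 of 16 higher, 0.00168, then 0.345) and Kupffer cells (1 of 16 higher, 0.00436, then 0.495). The count was 1028 genes, 540 higher and 488 lower (63 and 32 by at least 2-fold), and 31.9% of all tested genes had non-overlapping groups (10% by chance). Among drug-processing genes 82 were higher and 9 lower (115 called when adjusted over the list alone). The count of all genes was 461 with the suffix as a factor, where CITCO replicate 1 alone stands for its group, 2139 with array weights and 1123 (57.1% higher against 52.5%) after rescaling. Lists of circadian clock, acute phase, uptake transporter, lymphocyte, cholangiocyte and pancreatic acinar genes were not called in any of the 4 treatment comparisons.

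The 4 treatment comparisons share no libraries, and both ages shared many responding genes. TCPOBOP raised 2076 genes at both ages, where independent sets would share 949, and lowered 712 (220 if independent). Of the genes it raised at day 5, 109 were lower at day 60 (479 if independent). CITCO raised 144 at both ages (45 if independent) and lowered 95 (43 if independent), while 35 raised at day 5 were lower at day 60 (40.0 if independent). Between the pairs, 402 genes rose with both ligands at day 5 (250.0 if independent), and 245 that rose with TCPOBOP were lower with CITCO (266 if independent). At day 60 the shared rises were 401 (169 if independent) and the opposite ones 92 (153 if independent). In all 4 comparisons 39 drug-processing genes were higher, among them Cyp2b10, Cyp2c55, Cyp3a11, Aldh1a7, Ces2a, Ephx1, Gstm3, Gsta1, Abcc3 and Abcc4, and 0 were lower.

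The TCPOBOP response differed between the ages (day 60 minus day 5 response in wild type). Here responding more or less means a higher or lower log2 response. It was higher in adults for Sult1e1 (4.58 ± 0.31), Akr1b7 (3.93 ± 0.29), Sult3a1 (3.88 ± 0.18), Cyp2b9 (3.84 ± 0.82), Cyp2b13 (3.39 ± 0.27) and Gsta1 (2.88 ± 0.26). It was lower in adults for Cyp2c29 (-5.11 ± 0.55), Slco1a1 (-4.14 ± 0.29), Aldh1a7 (-3.10 ± 0.23), Cyp2c54 (-2.88 ± 0.53), Cyp2c67 (-2.85 ± 0.17) and Cyp2c50 (-2.83 ± 0.57). Cyp2b10 itself was not called (-0.77 ± 0.36, limma adjusted p = 0.144). Cell cycle genes responded more in adults in 40 of 42 cases (camera adjusted p = 3.87e-42, and adjusted p = 0.0198 with an estimated correlation). P450 genes responded less in 29 of 47 and more in 7 (2.56e-10, and 0.0162 with an estimated correlation). Other conjugation enzymes responded less in 12 of 17 and more in 2 (1.22e-06, and 0.0115 with an estimated correlation), and bile acid synthesis genes less in 9 of 15 and more in 1 (6.75e-05, and 0.00895 with an estimated correlation). Female-biased genes responded more in 9 of 14 (2.54e-07, and 0.0162 with an estimated correlation). Male-biased genes responded less in 7 of 15 (1.13e-07, and 0.129 with an estimated correlation). Starting levels differed: under corn oil, 15 of 15 male-biased genes were higher and 41 of 42 cell cycle genes lower in adults (rescaled values). Also higher in adults were 40 of 47 P450 genes (5 lower), 14 of 17 other conjugation genes (1 lower) and 11 of 15 bile acid synthesis genes (1 lower). Differences between the ages in these lists may therefore partly reflect the starting level. The response differed in 2879 genes, 1680 upward and 1199 downward (53.4% upward after rescaling against 58.4%). The count was 5037 with array weights, and the suffix cannot be told apart from the groups in this comparison. Among drug-processing genes, 38 differed upward and 91 downward (143 called when adjusted over the list alone).

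For CITCO in hCAR-TG mice the rise of Cyp2b10 was much smaller at day 60 (-4.54 ± 0.36, limma adjusted p = 2.34e-07), from a corn oil level that was higher in adults. Cyp2c29 (-5.22 ± 0.55), Cyp2c50 (-3.73 ± 0.57), Cyp2c54 (-3.38 ± 0.53), Sult2a5 (-2.66 ± 0.14) and Bhmt (-2.16 ± 0.22) also responded less, while Gsta1 (3.29 ± 0.26), Akr1b7 (2.51 ± 0.29), Gstm3 (2.45 ± 0.20) and Cyp3a16 (2.26 ± 0.21) responded more. Under corn oil, 35 of 47 P450 genes were higher in adults and 9 lower, and 16 of 17 other conjugation genes higher and 1 lower (rescaled values). Age differences of genes in these lists may therefore partly reflect the starting level. Glutathione S-transferase genes responded more in 9 of 27 cases (camera adjusted p = 8.51e-07, and adjusted p = 0.0881 with an estimated correlation) and endothelial markers in 9 of 16 (4.16e-09, then 0.0881). Lipogenic genes responded less in 5 of 17 (0.000463, then 0.316). The response differed in 1227 genes (660 upward, 567 downward, and 63.7% upward after rescaling against 53.8%), including 41 drug-processing genes upward and 28 downward (91 called when adjusted over the list alone). The count was 814 without CITCO day 5 replicate 3, 3279 with array weights and 3292 (37.4% upward) with the suffix as a factor, which rests on corn oil day 5 replicate 3 and CITCO day 60 replicate 1.

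**Figure D3:**
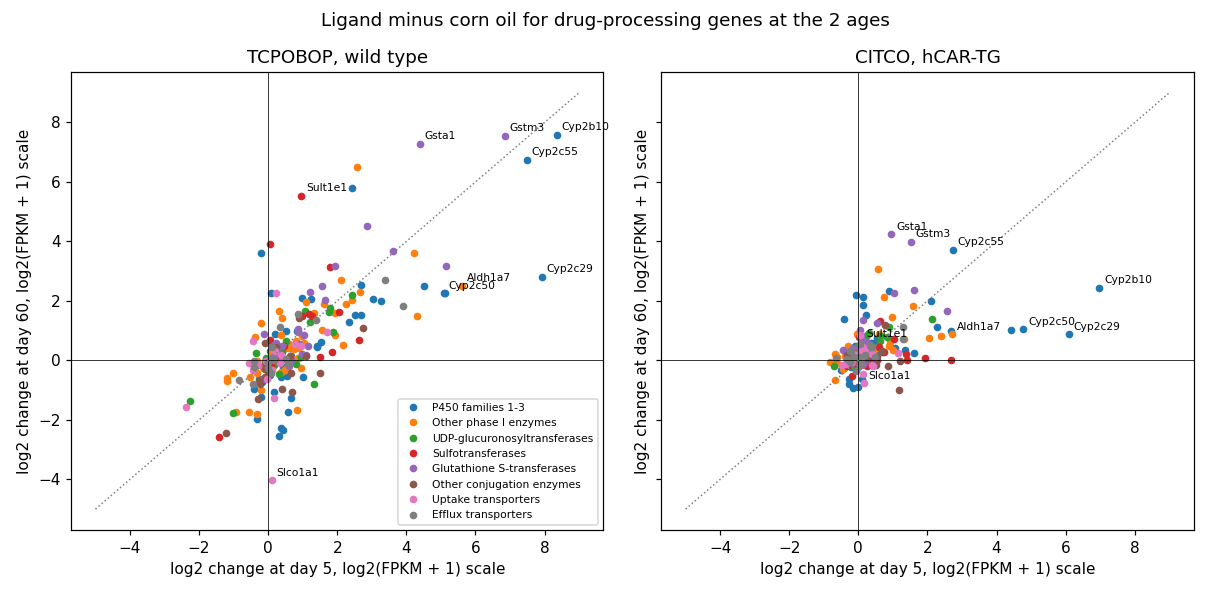
Log2 change with the ligand at day 60 against day 5 for the tested drug-processing genes, coloured by family. Points on the dotted diagonal changed equally at the 2 ages.

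The CITCO response in hCAR-TG mice was smaller than the TCPOBOP response in wild type mice for most CAR targets. Doses are not given, so size alone does not rank the receptors. At day 5 the difference (hCAR-TG minus wild type response) was -1.38 ± 0.36 for Cyp2b10 (limma adjusted p = 0.00749), -5.32 ± 0.20 for Gstm3, -4.76 ± 0.23 for Cyp2c55, -4.30 ± 0.31 for Cyp2a5, -3.44 ± 0.26 for Gsta1, -3.10 ± 0.37 for Cyp2a4 and -2.90 ± 0.23 for Aldh1a7. It was positive for Slc22a7 (2.76 ± 0.20), Bhmt (2.37 ± 0.22), Ugt3a2 (1.58 ± 0.17), Sult2a8 (1.11 ± 0.24), the dioxin-inducible P450 gene Cyp1a1 (1.09 ± 0.08) and Cyp2j9 (0.92 ± 0.22). CAR targets responded less in 22 of 35 cases (camera adjusted p = 3.41e-12, and adjusted p = 0.0438 with an estimated correlation), glutathione S-transferases in 19 of 27 (1.91e-08, and 0.0438 with an estimated correlation) and NRF2 targets in 10 of 14 (4.26e-05, and 0.0438 with an estimated correlation). P450 genes did so in 23 of 47 with 2 opposite (0.000159, and 0.225 with an estimated correlation). The pairs differed in 4142 genes, 1413 upward and 2729 downward (drug-processing genes 23 and 102; 130 called when adjusted over the list alone). Leaving out the 3 newborn libraries with pancreatic transcripts, chosen after seeing the data, gave 2532; array weights gave 6352. Rescaled values gave 4092 with 43.7% upward against 34.1%.

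At day 60 the difference was -5.15 ± 0.36 for Cyp2b10 (limma adjusted p = 2.73e-09), -4.91 ± 0.31 for Sult1e1, -3.73 ± 0.18 for Sult3a1, -3.58 ± 0.20 for Gstm3, -3.46 ± 0.27 for Cyp2b13 and -3.41 ± 0.29 for Akr1b7. It was positive for Slco1a1 (3.27 ± 0.29), Sult2a8 (2.40 ± 0.24), Cyp2c44 (2.03 ± 0.18), Cyp2e1 (1.93 ± 0.15), Ces3b (1.70 ± 0.19) and the aldehyde oxidase gene Aox3 (1.69 ± 0.15). Cell cycle genes were lower on this scale in 41 of 42 cases (camera adjusted p = 1.35e-30, and adjusted p = 0.0739 with an estimated correlation), CAR targets in 26 of 35 with 1 higher (2.69e-10, then 0.0739), lipogenic genes in 13 of 17 (5.46e-06, then 0.16) and cholesterol synthesis genes in 21 of 24 (3.23e-06, then 0.317). Male-biased genes were higher in 9 of 15 (6.8e-07, then 0.165). Under corn oil at this age, Cyp2b10, Cyp2b13, Gstm3 and part of the lipogenic genes were already higher in hCAR-TG than in wild type. Their lower values on this scale partly reflect that starting level, which makes up most of the difference for Cyp2b10. The pairs differed in 4154 genes, 1200 upward and 2954 downward (drug-processing genes 59 and 70; 138 called when adjusted over the list alone). The deposited minus the rescaled log2 value had a median of -0.108 here, and rescaling gave 4201 genes with 46.8% upward against 28.9%.

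Under corn oil at day 5, hCAR-TG livers differed from wild type in blood cell, intestinal and drug-processing genes. Higher were Car1, a carbonic anhydrase of red cells and colon (3.40 ± 0.27), the cathepsin gene Ctse (2.99 ± 0.16), Lypd8 (3.04 ± 0.23), the mucosal peptide gene Tff3 (2.85 ± 0.41) and Defa24 (2.73 ± 0.29). Lower were Nr1i3 (-1.34 ± 0.18; 58.0 ± 12.8 in wild type, 22.3 ± 4.78 in hCAR-TG), Cyp2c29 (-2.16 ± 0.39), the eosinophil ribonuclease gene Ear1 (-2.04 ± 0.51), Cyp2c50 (-1.58 ± 0.41) and Sult2a5 (-1.44 ± 0.10). Cyp2b10 was not called (-0.58 ± 0.26, limma adjusted p = 0.169). Erythroid markers were higher in 15 of 16 cases (camera adjusted p = 9.31e-25, and adjusted p = 0.0215 with an estimated correlation), such as Trim10 (1.59 ± 0.12), and sulfotransferases lower in 6 of 17 (3.34e-06, and 0.0296 with an estimated correlation). Neutrophil markers were higher in 13 of 14 (2.67e-13, and 0.135 with an estimated correlation) and fetal genes in 7 of 15 (0.00391, and 0.0611 with an estimated correlation), including Afp (1.10 ± 0.14). Pancreatic acinar genes were lower as a list (0.000397, and 0.735 with an estimated correlation) with 0 of 17 called, and wild type replicate 2 holds the highest values of these 6 libraries for most of them (Ctrb1 103 FPKM, against 12.1 or less in the others). The count was 1297 genes (1018 higher, 279 lower), including 26 drug-processing genes higher and 17 lower (61 called when adjusted over the list alone). Of all tested genes 21.7% had non-overlapping groups (10% by chance). The count was 801 without wild type replicate 1 and again 801 without replicate 2. It was 191 in a fit of these libraries alone, 4571 with array weights, 817 with the 5 FPKM filter, 785 without the pancreatic libraries, and 1117 (63.3% higher against 78.5%) after rescaling. A mixed split of the same 6 libraries, with hCAR-TG replicate 3 beside wild type replicates 1 and 2, called 1057 genes. Without hCAR-TG replicate 3, which stands apart, 1745 genes were called, and 996 of the 1297 kept call and direction.

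Under corn oil at day 60, Cyp2b10 was at 225 ± 16.5 FPKM in hCAR-TG against 12.9 ± 4.16 in wild type (4.07 ± 0.26; n = 3 per group, limma adjusted p = 5.36e-09). Ctse (3.77 ± 0.16), Lrtm1 (2.01 ± 0.19), Cyp2b13 (2.01 ± 0.19), the ferritin receptor gene Scara5 (1.68 ± 0.20), Gstm3 (1.19 ± 0.14) and Gstm2 (1.01 ± 0.13) were also higher. Nr1i3 was lower (-2.83 ± 0.18; 68.2 ± 12.9 against 8.70 ± 1.56 FPKM), as were Derl3, a gene of protein degradation at the endoplasmic reticulum (-2.66 ± 0.14), Cebpe (-1.97 ± 0.20), the clock-controlled gene Dbp (-1.73 ± 0.42), Cyp3a59 (-1.47 ± 0.09) and Cyp2c40 (-1.31 ± 0.10). Tomm40l, also lower (-1.58 ± 0.16), overlaps Nr1i3 on chromosome 1 over 1043 bp, so reads may be shared. Lipogenic genes were higher in 7 of 17 cases (camera adjusted p = 9.54e-09, and adjusted p = 0.235 with an estimated correlation), including Acss2 (1.25 ± 0.15). PPARa and fatty acid oxidation genes were lower in 6 of 34 (1.1e-09, then 0.235). CAR targets were higher in 6 of 35 with 1 lower (0.000279, then 0.235), and P450 genes lower in 8 of 47 with 3 higher (0.00112, then 0.235). The count was 602 genes (375 higher, 227 lower), with 18 drug-processing genes higher and 15 lower (56 called when adjusted over the list alone). Of all tested genes 24.9% had non-overlapping groups (10% by chance). The count was 336 without hCAR-TG replicate 1, 361 without wild type replicate 2, 230.0 in a fit of these libraries alone, 1579 with array weights, 691 (59.6% higher against 62.3%) after rescaling and 109 (73.4% higher) with the suffix as a factor. That last count hangs on wild type TCPOBOP replicate 3, the library that sets the suffix effect.

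From day 5 to day 60 under corn oil, both genotypes gained adult liver genes and lost fetal genes. In wild type mice the urinary protein genes Mup7 (11.77 ± 0.47) and Mup20 (11.21 ± 0.55), Ces3b (6.89 ± 0.14), Scd1 (6.80 ± 0.21), Aldh1a1 (6.72 ± 0.18), Slco1a1 (6.46 ± 0.21) and Cyp3a11 (3.20 ± 0.11) rose. The fetal genes H19 (-12.62 ± 0.13), Afp (-11.39 ± 0.14), Igf2 (-10.33 ± 0.09) and Gpc3 (-6.54 ± 0.16) fell with the female-biased sulfotransferase genes Sult2a2 (-7.82 ± 0.16) and Sult2a1 (-7.25 ± 0.18). Cyp2b10 rose by 1.38 ± 0.26 in wild type and by 6.03 ± 0.26 in hCAR-TG mice, and Nr1i3 was at 0.23 ± 0.18 (limma adjusted p = 0.253) and -1.25 ± 0.18 (limma adjusted p = 3.54e-06). In hCAR-TG mice Mup7 (11.79 ± 0.47) and Scd1 (8.14 ± 0.21) rose, and H19 (-12.68 ± 0.13), Afp (-12.09 ± 0.14) and the granulocyte gene Ngp (-7.03 ± 0.24) fell. The P450 list was higher in 38 of 47 with 6 lower in wild type (camera adjusted p = 5.74e-14, and adjusted p = 0.00381 with an estimated correlation) and in 35 with 11 lower in hCAR-TG (4.76e-11, and 0.00785 with an estimated correlation). UDP-glucuronosyltransferases rose in 18 of 20 (1.56e-12, and 0.00692 with an estimated correlation) and 19 of 20 (3.01e-13, and 0.00522 with an estimated correlation), and male-biased genes in 15 of 15 in both (8.16e-14 and 6.78e-14, and 0.0272 and 0.0255 with an estimated correlation). Fetal genes fell in 15 of 15 and 14 of 15 (4.1e-09 and 2.03e-08, and 0.000702 and 0.000874 with an estimated correlation). Cell cycle genes fell in 41 of 42 in both (5.74e-14 and 6.78e-14, and 0.147 and 0.148 with an estimated correlation). Erythroid markers fell in 15 of 16 with 1 higher (0.00246, and 0.341 with an estimated correlation) and in 16 of 16 (1.56e-06, and 0.148 with an estimated correlation). These lists kept their direction after rescaling. The deposited minus the rescaled log2 change had a median of -0.154 in wild type and -0.191 in hCAR-TG. Wild type had 8617 genes called (3101 higher, 5516 lower, 148 drug-processing genes higher and 46 lower, 195 called when adjusted over the list alone) and hCAR-TG 8788 (2979 higher, 5809 lower, 150 and 48, 199 called when adjusted over the list alone). Of all tested genes 74.3% and 70.5% had non-overlapping groups (10% by chance). Rescaled values gave 8814 with 49.5% higher and 8929 with 50.2% higher, and the 5 FPKM filter gave 5568 and 5688 among fewer tested genes.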

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

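The responses differed between ages and between pairs of receptor and ligand when tested as interactions in limma, and the differences are given first as values. The split tests of the counts and the first test of intestinal tissue were written before their results were seen, and the other 5 tests were chosen after the result was seen.

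The TCPOBOP response differed between ages in 2879 genes: Sult1e1 4.58, Akr1b7 3.93, Sult3a1 3.88, Cyp2b9 3.84, Cyp2b13 3.39, Gsta1 2.88, Cyp2c29 -5.11, Slco1a1 -4.14, Aldh1a7 -3.10, Cyp2c54 -2.88, Cyp2c67 -2.85 and Cyp2c50 -2.83 (log2, day 60 minus day 5). The CITCO response differed between ages in 1227 genes: Cyp2b10 -4.54, Gsta1 3.29, Akr1b7 2.51, Gstm3 2.45, Cyp3a16 2.26, Cyp3a41a 1.97, Cyp2a4 1.82, Cyp2c29 -5.22, Cyp2c50 -3.73, Cyp2c54 -3.38, Sult2a5 -2.66 and Bhmt -2.16. The pairs of receptor and ligand differed at day 5 in 4142 genes: Cyp2b10 -1.38, Slc22a7 2.76, Bhmt 2.37, Ugt3a2 1.58, Sult2a8 1.11, Cyp1a1 1.09, Cyp2j9 0.92, Gstm3 -5.32, Cyp2c55 -4.76, Cyp2a5 -4.30, Gsta1 -3.44, Cyp2a4 -3.10 and Aldh1a7 -2.90 (hCAR-TG minus wild type). They differed at day 60 in 4154 genes: Cyp2b10 -5.15, Slco1a1 3.27, Sult2a8 2.40, Cyp2c44 2.03, Cyp2e1 1.93, Ces3b 1.70, Aox3 1.69, Sult1e1 -4.91, Sult3a1 -3.73, Gstm3 -3.58, Cyp2b13 -3.46 and Akr1b7 -3.41.

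Of 100 drawn label swaps, the real one included, the count was reached in 7 for TCPOBOP between ages (highest other 6568), 1 for CITCO between ages (highest other 657), 1 for the pairs at day 5 (highest other 3207) and 3 for the pairs at day 60 (highest other 4830). The 6 other swaps that reached the TCPOBOP count exchange treated and control labels in the whole adult arm and keep 2 or 3 of the 3 newborn TCPOBOP libraries, so they add the adult response to part or all of the newborn one. A share of 7 in 100 lies above the bound of 0.05 set in advance, so this test does not exclude chance for the TCPOBOP count between ages. It cannot show chance either, because swapped treatment labels ask whether there is any response, not whether responses differ. For the same reason the shares of the other differences decide nothing on chance. For each pair of groups only 10 splits exist, too few for a share under 0.05. The real split was the highest in all 8: TCPOBOP 4408 at day 5 (highest other 0) and 5801 at day 60 (1), CITCO 2099 (11) and 1028 (17), genotypes 1297 (1057) and 602 (3), ages 8617 (1) and 8788 (4).

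The first pattern weighed is the intestinal genes of the newborn hCAR-TG corn oil libraries. Of 21 listed intestinal genes, 10 were higher in all 3 of these libraries than in each of the other 21 libraries, and 17 had their highest group mean there. Chance would give 0.010 of the former if all libraries were interchangeable, which libraries of different groups and ages are not. All of the 10 except Lyz1 stayed under 1 FPKM in these 3 libraries. The 10 lie between the bounds set in advance, so intestinal tissue in the samples remains possible and is not shown. A trait of the genotype at day 5 under both treatments stays open too: over the 21 listed genes, the CITCO libraries of the same genotype and age held a median of 11.4% of the corn oil level, with 10 under 10% and Mep1a and Cdhr5, named after their values were seen, at 100% or more. An effect of CITCO on these genes cannot be told apart from a difference in dissection.

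The second pattern is the rise of cell cycle genes with TCPOBOP in adult wild type mice. A rise in the number of blood or immune cells is argued against, since the highest of the 4 medians of their lists was -0.006 (log2). These medians cannot show whether such cells already present began to cycle, so that source stays open. Scaling of the libraries is argued against too, since the median of the cell cycle list was 2.17 after rescaling. A response of the liver cells to TCPOBOP could account for the rise, but no measurement here separates hepatocytes from other cells. Lists of other liver cells were left out of this test. After rescaling, endothelial markers were higher in 4 of 16 and lower in 4. Stellate cell markers were higher in 2 of 15 and lower in 4, and cholangiocyte markers higher in 3 of 12 and lower in 1.

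The last pattern is the level of Cyp2b10 in adult hCAR-TG corn oil libraries. Reads of paralogs stay open: Cyp2b9 and Cyp2b13 together reach 3.48% of Cyp2b10, but reads counted as Cyp2b10 would also lower these paralogs, so the bound set for this test was wrong. RNA of CITCO-treated livers mixed into these libraries stays open only for a part of the level. The share implied by Cyp2b10 was 17.5% and the median over 53 other induced genes was 5.41%. Single genes among these ranged from -18.8% for Cyp2a5 to 33.0% for Smpd3. The 8 genes that CITCO raised more than Cyp2b10 lie from 1.18% (Gsta1) to 3.74% (Cyp2c55). A larger rise with CITCO forces a lower share, so their choice put them under Cyp2b10 in advance. A rise as large as that of Gsta1 does go against a single share of 17.5% in all genes, since mixing would hold it down. A smaller share stays open, but it would give less Cyp2b10 than was seen. All these shares take wild type as the unmixed level. Basal activity of the human receptor in adults might also give this level, and it was not tested.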

How the results depend on the processing

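Of the 848 values of named genes, 829 kept direction and call after rescaling (19 weaker), 822 with a pseudocount of 0.1 (26 weaker), 822 without a filter (26 weaker), 775 of 776 with the 5 FPKM filter, 840 with array weights, 847 with a constant prior, 690 in fits of the compared libraries alone (157 weaker) and 521 when a 2-fold change was also required (327 weaker). Leaving out a replicate kept 4924 of 5388, and leaving out the pancreatic libraries, chosen after seeing the data, kept 410 of 454. With the suffix as a factor 403 of 515 kept direction and call, 111 were weaker and 1 reversed: Nr1i2 with CITCO at day 5, not called before or after, at -0.037. In the order of the report (TCPOBOP at days 5 and 60, CITCO at days 5 and 60, the age differences of TCPOBOP and CITCO, the pair differences at days 5 and 60, genotypes at days 5 and 60, ages in wild type and hCAR-TG), requiring a 2-fold change gave 391, 834, 116, 95, 534, 164, 378, 736, 130.0, 56, 1995 and 2264 genes, by its own construction. Array weights gave 6665 for TCPOBOP at day 5, 5259 and 2139 for CITCO, 5037 and 3279 for the age differences, 6352 for the pairs at day 5, and 4571 and 1579 for genotypes. The compared libraries alone gave 596 for CITCO at day 5 and 191 and 230.0 for genotypes, with fewer samples. The suffix factor gave 4793 and 461 for CITCO, 3292 for its age difference and 109 for genotypes at day 60. For CITCO at day 5 that contrast rests on corn oil replicate 3, at day 60 on CITCO replicate 1, for the age difference on both, and for genotypes at day 60 the suffix effect comes from wild type TCPOBOP replicate 3. The 5 FPKM filter gave 817 for genotypes at day 5, and 5568 and 5688 for ages, among fewer genes (7823). Leaving out the pancreatic libraries gave 2532 for the pairs and 785 for genotypes at day 5. Except where the construction shows it, the cause was not tested.

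Leaving out each replicate in turn gave, in the same order, 3577 to 4289, 5074 to 5639, 1147 to 2633, 703 to 803, 2385 to 2828, 814 to 1372, 3351 to 4624, 3597 to 4361, 801 to 1745, 336 to 742, 8153 to 8286 and 8309 to 8947 genes. All other counts stayed within 1.5 times the reported value. With an estimated correlation the number of called lists fell from 12 to 6, 15 to 3, 12 to 2, 17 to 10, 15 to 5, 14 to 0, 12 to 3, 17 to 0, 10 to 2, 12 to 0, 23 to 9 and 22 to 10. With fry it rose from 12 to 24 for TCPOBOP at day 5.

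A replicate block gave 4343, 5763, 2005, 976, 2822, 1139, 4007, 4078, 1219, 582, 8574 and 8765 genes in the same order. Correlations of the 12 same-numbered pairs ran from -0.14 to 0.264, so the replicate numbers show no clear pairing. With 3 replicates per group this cannot exclude that samples were paired. The sex covariate was not run, because all libraries are male, nor was the suffix factor for TCPOBOP at day 5, its age difference, the pairs and genotypes at day 5 and ages in hCAR-TG, where it cannot be told apart from the groups. Depth is unknown, so genes near 1 FPKM may be missed in any comparison. Without a filter 4851 genes were called for TCPOBOP at day 5 and 1653 for genotypes at day 5, among 19722 tested.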

Other observations

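In adult male livers given TCPOBOP, 9 of 15 male-biased genes fell and 10 of 14 female-biased genes rose, but neither list kept its call with an estimated correlation (camera adjusted p = 0.183 and 0.0602). Cyp2d9, which is male-biased, rose (0.41 ± 0.17), and the female-biased genes Fmo2 (-0.44 ± 0.15) and Acot3 (-0.48 ± 0.19) fell, all 3 named after their values were seen. Besides Hsd3b5, the male-biased genes Nudt7 (-2.54 ± 0.17), Cyp7b1 (-2.43 ± 0.22) and Susd4 (-2.23 ± 0.20) fell, and the female-biased genes Cyp2b13 (5.81 ± 0.19), Sult1e1 (5.54 ± 0.22), Sult3a1 (3.92 ± 0.13) and Hao2 (2.63 ± 0.08) rose. With CITCO in adult hCAR-TG mice Cyp3a41a (2.12 ± 0.20), Cyp3a44 (1.84 ± 0.11) and Cyp2a4 (1.41 ± 0.26) rose, and of 15 male-biased genes 2 fell, Nudt7 (-0.61 ± 0.17) and Slco1a1 (-0.77 ± 0.21), and 2 rose, Cyp2d9 (0.57 ± 0.17) and Ugt2b38 (0.42 ± 0.11), the latter pair named after their values were seen. The adipose list had 4 tested members, of which Fabp4 (0.90 ± 0.25) rose and Lipe (-0.36 ± 0.13) fell with TCPOBOP in adults.

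In the immediate early and heat shock, acute phase and clock lists genes moved both ways, and none of the 3 lists was called with TCPOBOP or with CITCO at day 60. The immediate early and heat shock list was called lower with CITCO at day 5, as given above. With TCPOBOP, Trib3 rose by 2.89 ± 0.27 at day 5 and Orm3 by 3.11 ± 0.25 at day 60, and Itih3 fell at both ages (-1.14 ± 0.07 and -1.60 ± 0.07). Of 22 acute phase genes 7 rose and 2 fell at day 5, and 7 rose and 7 fell at day 60. With CITCO at day 60, Hspa5, the chaperone of the endoplasmic reticulum, fell (-0.94 ± 0.17), while 3 genes of its list rose and 2 fell. Of 16 clock genes 4 fell, among them Nfil3 (-0.92 ± 0.17) and Npas2 (-0.77 ± 0.15), and 4 rose, among them Dbp (1.75 ± 0.42) and Nr1d1 (1.30 ± 0.31), both named after their values were seen.

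Pancreatic acinar genes were high in 3 newborn libraries of different groups (wild type corn oil replicate 2, wild type TCPOBOP replicate 2 and hCAR-TG CITCO replicate 1): 16 of 18 lay above each of the other 21 libraries. Prss2 was at 30.8, 28.4 and 30.5 FPKM there and at most 2.96 elsewhere, and Ctrb1 at 103, 191 and 167 against at most 14.5. Intestinal genes were high in the 3 newborn hCAR-TG corn oil libraries: Lypd8 6.28, 10.8 and 16.4 FPKM (at most 1.13 elsewhere) and Defa24 3.03, 5.95 and 14.5 (at most 0.495).

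The split of newborn corn oil libraries that called 1057 genes set wild type replicates 1 and 2 with hCAR-TG replicate 3 against the rest. Tomm40l, which overlaps Nr1i3, changed by -0.80 and -1.30 with TCPOBOP at days 5 and 60 (limma adjusted p = 0.000498 and 8.35e-07), and by 0.39 and -0.10 with CITCO (limma adjusted p = 0.0944 and 0.818). Cyp2b10 lies on chromosome 7 at 25897658 to 25926624 and Cyp2b13 at 26061495 to 26096196.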
